A study of Macaca mulatta with 14 samples.

How the data were processed

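Small RNA was sequenced from post-mortem testis of 12 male rhesus macaques. The organism, title, source and treatment labels name this species, while the sample descriptions speak of human individuals; the species was taken from the former and was not tested. Per the labels' protocols, total RNA was extracted with Trizol from frozen tissue, and low molecular weight RNA was ligated to adapters, amplified and sequenced on an Illumina Genome Analyzer with the Illumina small RNA kit. The series holds 14 libraries: the animals of 16 and 1487 days each gave 2 technical libraries, and the other animals gave 1 each. The submitters' processing notes name CASAVA 1.4 and Bowtie without a role. The genome build, the miRNA annotation and the alignment settings are not given in the sources used here.

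The authors deposited 1 table of 538 miRNA names, written with the human prefix, in RPM (reads scaled to a fixed library total). The labels do not say which reads make up that total. Within each library every value was a whole multiple of the value of 1 read: 100% of the values came out whole within 0.01 reads, so whole reads and the total behind the scaling could be recovered. Those totals ran from 3369245 to 5620503 reads per library, and the listed miRNAs held 505943 to 4164799 of them, with the shared pairs described next counted once. These are PCR reads without molecular identifiers, so read numbers describe counting error only. The pairs miR-199a-3p with miR-199b-3p and miR-513b with miR-513c had read numbers equal within 2% in all libraries, among names with at least 1000 reads in total, and were counted once in the listed share. That minimum was raised from 50 reads after the data were seen; at 50 reads miR-520d-5p and miR-527, with 63 reads each, form a further pair, which was not counted once and stayed in the C19MC list under both names. Members of similar families, such as let-7 and C19MC, can share reads, and their separate values are uncertain for that reason.

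Animals were grouped from the age labels alone, with stage boundaries set for this work: neonate, juvenile, peripubertal, adult and aged, joined into immature (neonate and juvenile, n = 5), peripubertal (n = 3) and mature (adult and aged, n = 4). Libraries numbered 1 to 7 and 8 to 14 were treated as library series 1 and 2. Technical libraries of an animal were averaged on the log scale and never counted as separate animals. The 2 technical libraries were compared with libraries of different animals.

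The main test was limma 3.58.1 (R 4.3.3) with trend and robust settings on log2(value + 1) of the deposited values, in 1 model of all 12 animals, with Benjamini-Hochberg adjustment and a threshold of 0.05. A miRNA was tested if it reached 1 RPM in at least 3 animals, which left 322. Fold changes are on the log2(value + 1) scale and understate those of low miRNAs. The contrasts were fixed before the data were examined, with the alternatives that are not described as added. Because the listed miRNAs took very different shares of the reads, results are also given after median scaling, in which each library was divided by the median of the 276 names seen in every library. edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads were added after the data were seen, as were values scaled to the listed miRNA reads and fits without the animals of 471 and 1487 days.

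Lists fixed before the data were examined covered the miR-34b/c and miR-449 family, the X-linked miR-506 family, the X-linked miR-888 cluster, other X-linked miRNAs, the miR-17-92 and related clusters, the miR-302 and miR-371 clusters, the miR-183 cluster, let-7, the imprinted DLK1-DIO3 and H19-IGF2 regions, the primate C19MC cluster, miR-202, miR-143 with miR-145, myomiRs, blood cell miRNAs, miR-126, the miR-200 family, neuronal miRNAs, miR-122, miRNAs linked to senescence, and miR-29. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a contrast. Membership and X linkage were taken from human names.

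miRNAs named in the text follow a rule fixed before the data were examined. For each contrast the rule took miRNAs past the threshold, with a mean of at least 10 RPM and with all animals of a stage above or below all of the other, ranked by absolute log2 fold change: the first 12 in each direction for mature versus immature and the first 6 for the others. It also took the 3 most abundant members of each list and the 5 most abundant miRNAs of each stage. Other miRNAs named are said to have been chosen after their values were seen.

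The tests were tried on simulated reads for the mature versus immature comparison, with 200 of the 322 miRNAs changed and 10 simulations. limma recovered 83.8% of the miRNAs raised by a factor of 4, 80.04% of those lowered to 0.25, 24.2% of those raised by a factor of 2 and 22.5% of those lowered to 0.5, with 2.38% false calls. In 200 simulations a list of 30 unchanged miRNAs was called at 0.05 in 0% of runs by camera and in 4% by fry. The simulated miRNAs varied independently, and all simulated libraries had the same total. In the data the correlation that camera estimated within lists was, for example, 0.295 for C19MC and 0.920 for let-7. The simulated rates therefore do not describe error where miRNAs move together. The share of reads in listed miRNAs was compared with exact two-sided permutation tests, and its relation to age with permutation tests (Python 3.11.15, SciPy 1.17.1).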

Results

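miRNA abundance was measured in testis tissue of 12 rhesus macaques aged 16 to 9518 days, as a time course over the lifespan. The immature stage held animals of 16, 20, 215, 471 and 739 days, the peripubertal stage animals of 1135, 1205 and 1487 days, and the mature stage adults of 2355 and 2570 days and aged animals of 8104 and 9518 days. Immature libraries held 4381953 to 5253505 reads, peripubertal libraries 4671416 to 5607623 and mature libraries 3369245 to 5620503.

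The listed miRNAs took 79.3% of the reads at 20 days and 9.00% at 8104 days, with each pair of names that shared reads counted once. The share was 46.1% ± 25.3 (SD, n = 5) in immature, 19.2% ± 7.91 (SD, n = 3) in peripubertal and 18.9% ± 10.5 (SD, n = 4) in mature testis. Mature and immature animals did not differ past the threshold in an exact two-sided permutation test (p = 0.0952, adjusted p = 0.333 over 5 comparisons), and the juvenile and neonate animals could not, since 10 splits allow no p below 0.1. Over the 12 animals the share fell with log2 age (Pearson r = -0.87, permutation p = 0.00095, adjusted p = 0.00285 over 3 relations; Spearman rho = -0.60, permutation p = 0.0429). Without the animals of 16 and 20 days r was -0.57. Within library series 1 r was -0.89 (n = 7, exact permutation p = 0.0313), but it was 0.067 without the animals of 16 and 20 days, so that relation rested on them. Within series 2 r was -0.91 (n = 7, exact permutation p = 0.00536), and -0.61 without the libraries of 16 and 8104 days.

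**Figure D1:**
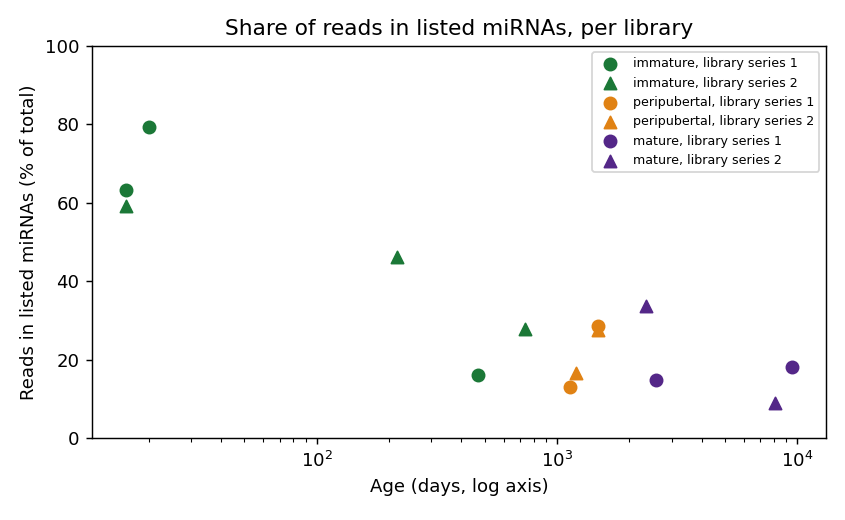
Percent of reads in listed miRNAs (vertical axis) against age in days (log horizontal axis), each point a library, coloured by stage, with circles for library series 1 and triangles for series 2. The library of 20 days lies highest, at 79.3%, and that of 8104 days lowest, at 9.00%.

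The 2 technical libraries of an animal were compared first, to set the technical part of the spread. Their Spearman correlation across miRNAs, which are not independent replicates, was 0.961 at 16 days and 0.957 at 1487 days. Among miRNAs of at least 10 RPM in both libraries, the median absolute log2 difference after median scaling was 0.300 at 16 days and 0.207 at 1487 days, against 0.247 to 0.590 between libraries of different animals of the same group. The libraries of an animal differed by more than counting error, with a chi-square per degree of freedom of 214 at 16 days and 66.0 at 1487 days. Between libraries of different animals of the same group it ran from 45.3 (215 and 739 days) to 681 (1135 and 1487 days), so these ranges overlapped. Each technical pair joined a library of series 1 with a library of series 2, so its spread also holds any difference between the series.

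let-7f was the most abundant miRNA in 13 of the 14 libraries, and miR-34c-5p was in that of 8104 days, at 22.9% of the listed reads. let-7f averaged 144651 ± 75989 RPM (SD, n = 5) in immature, 57315 ± 27196 (SD, n = 3) in peripubertal and 50715 ± 30785 (SD, n = 4) in mature testis. let-7g and let-7a were among the 5 most abundant names of each stage, and miR-199a-3p and miR-199b-3p among those of immature and peripubertal testis. In mature testis let-7c was among them, as was miR-34c-5p at 22668 ± 10396 RPM (SD, n = 4).

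Mature was compared with immature testis to find miRNAs that differ between these stages. The immature stage joins neonates and juveniles, which themselves differed in 104 miRNAs as deposited. A difference from mature testis therefore need not arise at puberty. The miR-34b/c and miR-449a/b family, known from meiotic and later germ cells, rose the most. miR-34c-5p averaged 271 ± 401 RPM in immature (SD, n = 5) and 22668 ± 10396 in mature testis (SD, n = 4), a log2 fold change of 7.27 (SE 0.949, limma adjusted p = 1.10e-05). Without the animal of 471 days, at 985 RPM, it was 7.98 (SE 0.844). miR-449a rose from 1.12 ± 1.47 to 82.0 ± 51.1 RPM and miR-34b* from 0.584 ± 0.976 to 63.7 ± 39.3 (SD, n = 5 and 4; log2 fold changes 5.35 and 5.34). All 6 tested members were called higher, also when adjusted over the list alone (6). The camera test called the list higher at the preset correlation (adjusted p = 2.63e-09), while with an estimated correlation its adjusted p = 0.0818.

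On the deposited scale most other miRNAs were lower: the median log2 fold change was -0.76, with 34 miRNAs called higher and 85 lower of 322. After median scaling the median was 0.096, with 76 called higher and 63 lower. On both scales 34 were called higher and 62 lower, and none was called in opposite directions. Groups are therefore given on both scales. Tested members of the primate-specific C19MC cluster were higher: 22 of 26 tested names were called on the deposited scale (23 adjusted over the list alone) and 25 after median scaling. The cluster had 51 names before the filter. Some, such as miR-520a-5p (mean 0.117 RPM in immature and 2.84 in mature testis), passed the filter only through animals past the immature stage. Many of the tested names had an immature mean below 1 RPM. The counts, and the camera and fry results of this list, therefore describe the names that passed and not the whole cluster. A filter met through the stage with higher values favours a call of higher values. The called names included miR-520d-5p and miR-527, whose reads were equal in each library (63 in total), so that this pair may be 1 measurement under 2 names. miR-1323 averaged 19.7 ± 5.92 RPM in immature (SD, n = 5) and 159 ± 72.3 in mature testis (SD, n = 4), and miR-520a-3p 1.32 ± 0.765 and 22.4 ± 13.3. miR-516b, with 14.05 ± 6.44 and 31.5 ± 3.17 RPM, was called after median scaling only (adjusted p = 0.00344). This was the only list of the contrast that kept its camera call with an estimated correlation (adjusted p = 0.0212), and after median scaling its adjusted p = 0.270 with an estimated correlation. miR-200a (log2 fold change 2.24, SE 0.568, adjusted p = 0.00414) and miR-429 (2.48, SE 0.400, adjusted p = 2.46e-05), both tested members of the miR-200 family known from epithelium, rose, with miR-200a at 55.5 RPM at 2355 days and at most 19.6 in the other mature animals. miR-7 rose from 67.1 ± 26.2 to 346 ± 294 RPM (log2 fold change 2.08, adjusted p = 0.0111), with 774 RPM at 2355 days and at most 296 in the other mature animals. Without the animal of 2355 days its log2 fold change was 1.57 (SE 0.578, adjusted p = 0.0395).

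miRNAs of the imprinted DLK1-DIO3 region were lower. Of 41 tested, 36 were called lower on the deposited scale (38 adjusted over the list alone) and 28 after median scaling, with none higher. The median log2 fold change of these names was -2.32 as deposited and -1.40 after median scaling. In juvenile versus neonate testis it was -2.53 and -1.18, so a fall of similar size also lay within the immature stage. miR-495 fell from 71.3 ± 62.6 to 4.31 ± 2.01 RPM (SD, n = 5 and 4), with a log2 fold change of -3.25 (SE 0.712) as deposited and -2.34 (SE 0.396) after median scaling. miR-136, miR-485-3p, miR-127-3p, miR-485-5p and miR-411 were called lower on both scales, miR-485-5p standing at 189 RPM at 2355 days and at most 42.2 in the other mature animals. Without the animal of 2355 days the log2 fold changes of miR-127-3p and miR-485-5p were -3.22 and -2.95, and without that of 8104 days both calls were lost (limma adjusted p = 0.0865 and 0.0547). That of miR-485-3p was -2.26 without the animal of 20 days. With an estimated correlation the list's adjusted p = 0.609, and after median scaling 0.270. miR-199a-3p fell from 78509 ± 53119 to 8861 ± 3627 RPM (log2 fold change -2.88, SE 0.648, adjusted p = 0.00145; -1.87, SE 0.209 after median scaling), and its reads were almost those of miR-199b-3p. miR-335, miR-181d, miR-199a-5p, miR-181c, miR-424*, miR-708 and miR-148a complete the largest falls, and each was called on both scales. Only 6 rises and 12 falls met the rule for the largest changes with full separation of 4 and 5 animals. Chance gives such a separation for 1.59% of miRNAs taken without selection. These counts come from miRNAs already selected by adjusted p and mean, so that rate is no measure for them.

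Of 10 tested let-7 names 7 were called lower (9 adjusted over the list alone) and 7 after median scaling, where let-7f differed by -0.52 (SE 0.142, adjusted p = 0.00759) and let-7g by -0.25 (adjusted p = 0.239). The camera call of let-7 was lost with an estimated correlation (adjusted p = 0.609). The median log2 fold change of the let-7 names was -1.58 as deposited and -0.62 after median scaling. In juvenile versus neonate testis it was -1.47 and -0.21. Of 35 other X-linked miRNAs 10 were called lower (8 adjusted over the list alone), and after median scaling 6 were lower and 2 higher. Among them miR-424 differed by -2.53 and by -1.53 after median scaling, and miR-503 by -1.79 (SE 0.715) and -0.79 (SE 0.373, adjusted p = 0.0969 after median scaling). With an estimated correlation the list's adjusted p = 0.628. In the miR-506 family, known from testis, 3 of 12 names were called lower (2 adjusted over the list alone) and 0 after median scaling, and these included the shared pair miR-513b and miR-513c. miR-510 averaged 1587 ± 681 and 807 ± 484 RPM (adjusted p = 0.166).

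In other lists more members were called after median scaling than as deposited. miR-143, miR-143* and miR-145, known from smooth muscle and peritubular cells, were among 4 of 4 members called higher on that scale and 0 as deposited. miR-143 averaged 4105 ± 3429 RPM in immature and 4916 ± 1882 in mature testis, a scaled log2 fold change of 1.62 (SE 0.339, adjusted p = 0.0016). The camera test called this list after median scaling (adjusted p = 0.0416) and not as deposited (adjusted p = 0.145), and the scaled call was lost with an estimated correlation (adjusted p = 0.302). Among the myomiRs 2 of 3 were called after median scaling, miR-1 (2.14, SE 0.367) and miR-499-5p (1.19), and miR-206, at 40.2 RPM at 215 days and at most 6.16 in the other immature animals, was not (0.046, adjusted p = 0.973). In the miR-29 family 3 of 4 and among the senescence miRNAs 5 of 9 were called higher after median scaling, with 0 as deposited. miR-29a, miR-29c and miR-29b had scaled log2 fold changes of 1.35, 1.56 and 1.84. The 2 lists overlap: all tested miR-29 names are also in the senescence list, and these 3 were among its 5 calls. The camera test called the senescence list (adjusted p = 0.0436) but not with an estimated correlation (adjusted p = 0.609). Of 7 neuronal miRNAs 1 was called as deposited and 5 after median scaling, with miR-128 at 1.47, miR-124 at 1.87 and miR-129-3p at 1.29. The camera call of that list was also lost with an estimated correlation (adjusted p = 0.609). In the miR-17-92 and related clusters 2 of 8 names were called higher after median scaling, with miR-92a at 0.94 and miR-25* at 1.18, and the deposited values of miR-92a differed by -0.046 and those of miR-25 by -0.42 without a call. miR-371-5p (2.41) and miR-372 (2.26), of clusters known from pluripotent cells and early germ cells, were both called after median scaling, and both when adjusted over the list alone on the deposited scale.

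Of 7 blood cell miRNAs 1 was called lower as deposited and 0 after median scaling, where miR-451 differed by -0.042, miR-142-5p by 1.23 and miR-486-5p by 0.35, each without a call. miR-126 and miR-126* of endothelium were not called on either scale (0.55 and 0.96 after median scaling). miR-122, known from liver and described in late spermatids, was called lower as deposited (-1.76, SE 0.709, adjusted p = 0.0498) but not after median scaling (-0.81, SE 0.562, adjusted p = 0.270). Its deposited value was low at 8104 days (6.05 RPM). miR-182 of the miR-183 cluster differed by -0.70 (adjusted p = 0.253), while miR-183 and miR-96 were below the filter. The X-linked miR-888 cluster, known from epididymis, had 0 members past the filter, and miR-891a reached at most 0.652 RPM. miR-675 of the H19 region and miR-200c were below the filter too, and the deposited names held no miR-202. The fry test, of whether the members of a list move on balance in a single direction, passed as deposited for C19MC (adjusted p = 0.000271) and the miR-34 family (adjusted p = 0.000533). It did not for DLK1-DIO3 and let-7 (adjusted p = 0.0689 for each), other X-linked (0.0936), neuronal (0.257) or senescence miRNAs (0.450). After median scaling it passed for each tested list but the miR-506 family (adjusted p = 0.595) and blood cell miRNAs (0.584). camera sets a list against the other miRNAs, and among the lists it did not call as deposited its direction could differ in sign from the list's median. This was so for the miR-17-92 and related clusters in mature versus immature, for the miR-506 family and myomiRs in peripubertal versus immature, for these, the neuronal and the senescence lists in juvenile versus neonate, and for the miR-34 family, DLK1-DIO3, C19MC, smooth muscle, myomiR and neuronal lists in aged versus adult. The senescence list in peripubertal versus immature had a mean below and a median above 0.

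The deposited calls of let-7f, let-7c, miR-503, miR-513b with miR-513c, and miR-122 were each lost without any single one of the animals of 16, 215, 8104 and 9518 days. Without that of 8104 days their limma adjusted p-values were 0.170, 0.162, 0.248, 0.159 and 0.199. Except for miR-513b and miR-513c, they were also lost without some of the other animals, and miR-503 was at -2.47 without that of 2355 days. Within library series 1 alone 12 miRNAs were called and within series 2 alone 63, in place of 119. The count was 70 without the animal of 16 days, 63 without that of 8104 days, 78 without that of 9518 days, and 166 without those of 471 and 1487 days, an alternative added after the data were seen.

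**Figure D2:**
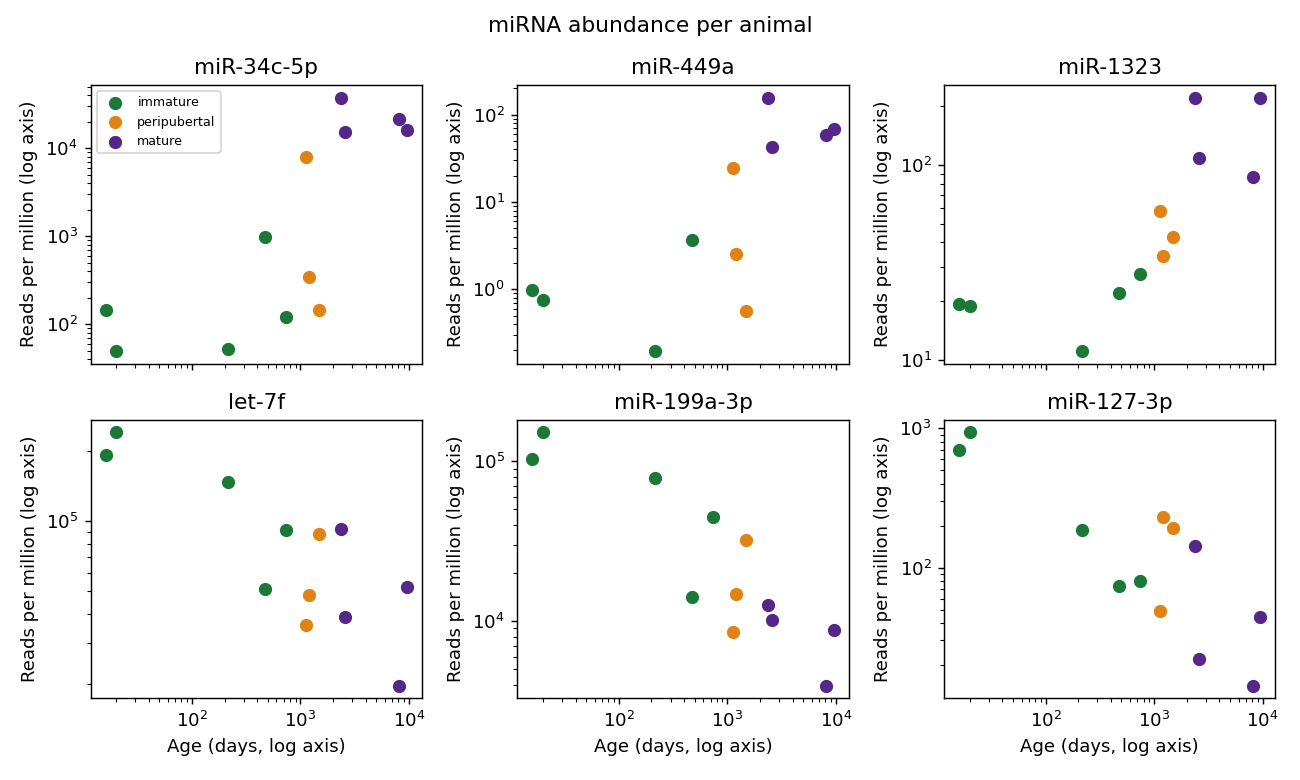
RPM (log vertical axes) of 6 miRNAs against age in days (log horizontal axes), each point an animal, coloured by stage, with technical libraries averaged and values of 0 not drawn (miR-449a at 739 days). miR-34c-5p was 985 at 471 days, 7887 at 1135 days and 147 at 1487 days, and at least 15138 in each mature animal.

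**Figure D3:**
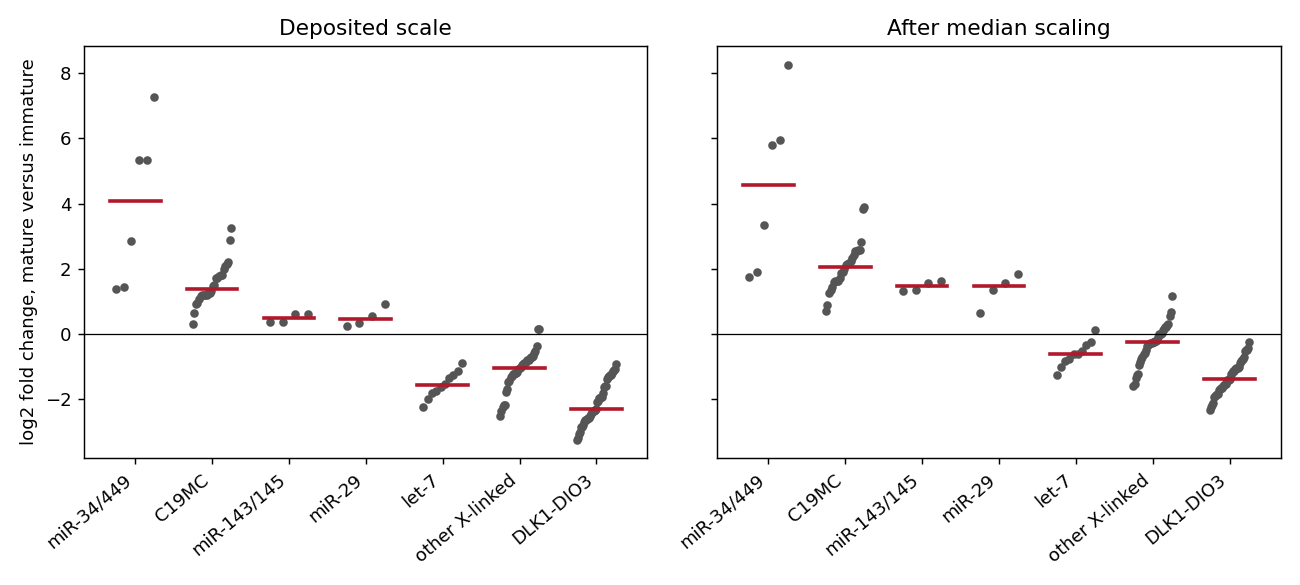
log2 fold change of mature against immature testis (vertical axes) for each tested member of 7 lists, as deposited on the left and after median scaling on the right, with a red line at the median of each list. The medians of the miR-34 and miR-449 family were 4.09 and 4.57, those of C19MC 1.38 and 2.05, and those of DLK1-DIO3 -2.32 and -1.40.

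Peripubertal was compared with immature testis to find changes at 3 to 4 years. No miRNA passed the threshold in limma: 0 of 322 were called and 50 had an unadjusted p under 0.05. miR-34c-5p averaged 2794 ± 4412 RPM (SD, n = 3) against 271 ± 401 (SD, n = 5), with a log2 fold change of 2.43 (SE 1.03, adjusted p = 0.302), since it was 7887 at 1135 days, 349 at 1205 days and 147 at 1487 days. After median scaling 3 were lower, miR-199a-3p and miR-199b-3p (-1.17 for each) and miR-708 (-1.56). edgeR called 0 with either normalization and DESeq2 22. Without the animal of 471 days limma called 60, of them 58 lower, and without those of 471 and 1487 days 69. The camera calls of this contrast were lost with an estimated correlation, the lowest adjusted p being 0.0551, for C19MC. fry called no list as deposited (lowest adjusted p = 0.337) and let-7 after median scaling (adjusted p = 0.0201).

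Mature was compared with peripubertal testis for changes after 4 years. 14 miRNAs were higher and 0 lower, with 33 at an unadjusted p under 0.05. miR-34c-5p (log2 fold change 4.84, SE 1.08, adjusted p = 0.00891), miR-34b* (3.86, SE 0.760, adjusted p = 0.00393) and miR-449a (3.82, SE 0.762, adjusted p = 0.00393) rose, and all 6 members of the family were called, also adjusted over the list alone. After median scaling the log2 fold change of miR-34c-5p was 5.10 with a wider spread (SE 1.88, adjusted p = 0.122), and 5 members were called. Of the C19MC names 4 were called (5 adjusted over the list alone). The camera calls of both lists had an adjusted p = 0.0699 with an estimated correlation, and those of DLK1-DIO3 and the miR-506 family, both toward lower values, an adjusted p = 0.714. fry passed for the miR-34 family and C19MC (adjusted p = 0.00868 for each), and after median scaling also for smooth muscle, myomiR and neuronal lists. Without the animal of 1135 days the log2 fold changes of miR-34c-5p, miR-34b* and miR-449a were 6.55, 5.14 and 4.96. Their limma adjusted p-values were 0.104, 0.0807 and 0.0807 without that of 1205 days, and 0.118, 0.0946 and 0.118 without that of 1487 days. The count was 0 without the animal of 1205 days and 0 without that of 1487 days, 0 with edgeR on all reads, 0 within series 1 and 9 within series 2.

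Juvenile was compared with neonate testis within the immature stage (3 animals against 2). As deposited 104 miRNAs were lower and 0 higher, with a median log2 fold change of -1.18. After median scaling 15 were lower and 8 higher. DLK1-DIO3 miRNAs fell: 40 of 41 were called (41 adjusted over the list alone), and 9 after median scaling. miR-889 differed by -3.62 (SE 0.757) and by -2.21 after median scaling (SE 0.514, adjusted p = 0.0221), and miR-433 by -3.49 and -2.05. miR-432, miR-130b, miR-299-3p and miR-487b were called lower on both scales. The list's adjusted p = 0.402 with an estimated correlation. All 7 tested blood cell miRNAs were called lower as deposited and 2 after median scaling, and that list's adjusted p = 0.402 with an estimated correlation. In the miR-29 family 2 of 4 were called higher after median scaling and 0 as deposited. The camera test at the preset correlation also called the miR-34 family, C19MC and miR-29 toward higher values relative to the other miRNAs. Their median log2 fold changes were 0.125, 0.274 and 0.092, with 0 members called as deposited, against -1.18 over all tested miRNAs. After median scaling the camera call of the miR-34 family was lost (adjusted p = 0.567), and those of C19MC (adjusted p = 9.15e-06) and miR-29 (adjusted p = 0.00338) stayed. With an estimated correlation as deposited, the camera adjusted p = 0.402 for the miR-34 family and miR-29 and 0.0913 for C19MC. fry passed for blood cell miRNAs (adjusted p = 0.00252) and DLK1-DIO3 (adjusted p = 0.0426), and after median scaling also for miR-29 (adjusted p = 0.0237). miR-889 was at -4.39 without the animal of 215 days and -2.70 without that of 471 days, and miR-487b at -3.62 without that of 215 days. miR-432 was at -4.31, -4.03 and -2.59 without the animals of 16, 215 and 471 days, and its call was lost without that of 20 days (-2.46, SE 0.971, adjusted p = 0.111). The count was 20 without the animal of 20 days, 67 without that of 16 days, 42 without that of 471 days and 57 without that of 739 days.

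Aged was compared with adult testis, 2 animals against 2. In limma 0 miRNAs were called and 11 had an unadjusted p under 0.05, and edgeR and DESeq2 also called 0. miR-34c-5p differed by -0.35 (SE 2.06, adjusted p = 0.930), miR-29a by -0.999 (SE 0.808, adjusted p = 0.679) and let-7f by -0.90 (SE 0.794, adjusted p = 0.679). No list was called at the preset correlation as deposited. After median scaling C19MC was (adjusted p = 0.0387), but not with an estimated correlation (adjusted p = 0.917). fry called no list (lowest adjusted p = 0.524 as deposited and 0.931 after median scaling).

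Across the 3 stages together 78 miRNAs changed in the F test, 28 higher and 50 lower in mature than in immature testis, and 64 and 51 after median scaling. Without single animals the count ran from 31 (8104 days) to 140 (471 days). It was 35 without the animal of 16 days, 36 without that of 2570 days, 34 without that of 9518 days, 41 without that of 215 days and 144 without those of 471 and 1487 days.

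Over age as a continuous axis 35 miRNAs rose and 180 fell with log2 age as deposited, and 67 rose and 72 fell after median scaling, where 39 of the 215 called values had the opposite sign. miR-34c-5p rose by 0.94 log2 units per doubling of age (SE 0.259, adjusted p = 0.00902) and miR-1323 by 0.36 (SE 0.0867). miR-199a-3p changed by -0.50 (SE 0.0721) and by -0.26 after median scaling, and miR-127-3p by -0.51 and -0.28. let-7f changed by -0.30 (SE 0.0674) as deposited and by -0.064 after median scaling (adjusted p = 0.0745).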

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

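The tests of scaling, library size, shared names, a wrong label, read number, library agreement and C19MC sequence series were chosen only after the results were seen. For 72 named miRNAs and the listed share, leaving out sets of equal values, 8 of 72 sets in the immature and 6 of 73 in the mature stage held an animal whose gap to the nearest other was too large for its stage. If values within a stage follow a normal distribution, chance gives about 1 in 20, or 7.25 of them, against the 14 found. The rule was applied to RPM and not to log values, and skewed values can raise the number found. No conclusion is drawn from the excess.

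In the immature stage the animal of 471 days stood above the others in miR-34c-5p (985 RPM, others 49.9 to 145.4), miR-449a (3.64) and miR-34b* (2.30). The animal of 20 days stood above in miR-432 (254), miR-126* (15.2) and miR-675 (5.14), that of 215 days in miR-206 (40.2) and that of 16 days in miR-96 (1.17). In the mature stage the animal of 2355 days stood above in miR-200a (55.5), miR-485-5p (189), and miR-486-5p (28.8). Without median scaling, the animal of 8104 days was low in miR-122 (6.05). In the mature stage miR-96 at 2355 days (0.297) and miR-892a at 8104 days (0.178) were each 1 read beside animals at 0, which gives such a gap by construction, so neither sets the animal apart.

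Most miRNAs had lower RPM values in mature testis. After median scaling 76 were called higher and 63 lower, so the excess of lower calls was gone; that scaling centres the values, so a single factor for each library and a true common shift cannot be told apart. Of the 85 lower calls 62 stayed, and those miRNAs were lower relative to the others as well. Library size differed little, with a ratio of mean reads of 0.922 against a median fold of 0.589. RPM values are already divided by the total of each library, so this comparison could not decide the question. Counting shared pairs once left the ratio of the listed share at 0.410. The common shift itself may reflect more of other small RNAs or RNA quality, neither of which was tested, or age. The listed share fell with log2 age (Pearson r = -0.87, permutation p = 0.00095, and r = -0.57 without the animals of 16 and 20 days). That relation does not separate age from the untested explanations.

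The miR-34 and miR-449 family was high at 1135 days and low at 1487 days. Neither few reads (1550 miR-34c-5p reads) nor a failed library (a ratio of 1.45 between the libraries) accounts for it. On 70 other miRNAs called higher in mature testis, the animal of 1487 days had a mean scaled log2 value of 3.09, under the highest immature animal at 3.38. That animal was the one of 471 days; the next, of 739 days, had 3.07, so the outcome rests on the 471-day animal, and the animal of 1205 days also lay low, at 3.21. A mislabelled immature animal would give this, and so would a late individual puberty, and no value here separates them.

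C19MC miRNAs that passed the filter were higher in mature testis. With a pseudocount of 0.1, 21 of the 22 names stayed called, so those calls did not rest on the pseudocount of 1. Names near the floor have little room to fall while most miRNAs fell. A smaller pseudocount cannot show whether that ranked the list high in camera, which was not tested. 5 called names lay outside the miR-515 to miR-527 series, which speaks against reads shared within that series as the whole source. An age-related rise in expression or a change in cell makeup stays open and was not tested.

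Splits of the animals into groups of the same sizes gave a limit on chance, each number of splits including the real one. For mature versus immature 4 of 100 splits reached the real count of 119, and 3 of them gave a higher count than the real split, up to 175. Because other groupings called more miRNAs, these splits do not exclude chance for the deposited count. After median scaling 1 of 100, the real split itself, reached 139 (highest other 118). For the 3 stages 3 of 100 reached 78 (highest other 128) and for the age trend 2 of 100 reached 215 (highest other 224). For mature versus peripubertal 1 of 35, the real split itself, reached 14 (highest other 3). For peripubertal versus immature the real count was 0, which all 56 splits reach by construction, so the splits say nothing about chance there (highest other 166).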

How the results depend on the processing

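Fits on recovered reads, scaled to listed reads, without the animals of 471 and 1487 days, and median shift with estimated correlation were chosen after the data were seen. No paired analysis was possible because the replicate numbers given in the labels mark the technical libraries of an animal and pair no animals across stages; library series entered as a term in a fit of all 14 libraries. A lone animal left in a group was assumed to vary like the others. The cause was not tested unless fewer miRNAs or animals entered.

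The 3-stage count (78) was 122 with quantile normalization, 49 without trend and robust settings, 30 with a pseudocount of 10, 22 with the 1487-day animal as mature, 139 with DESeq2, 126 scaled to listed reads and 144 without the animals of 471 and 1487 days; leaving out single animals gave 31 to 140. Mature versus immature (119) was 68 with a filter of 10 RPM, 12 and 63 within library series 1 and 2, and 63 to 165 without single animals. Peripubertal versus immature (0) was 3 after median shift, 22 with DESeq2, 69 without the 2 animals and 0 to 60 without single animals. Mature versus peripubertal (14) was 23 with quantile normalization, 5 with the filter of 10, 9 without trend and robust settings, 4 with a pseudocount of 0.1, 9 with all 14 libraries and a series term, 0 with the 1487-day animal as mature, 0 and 9 within series 1 and 2, 0 and 4 with edgeR on all reads and with TMM, 22 with DESeq2, 5 without the 2 animals and 0 to 14 without single animals. Juvenile versus neonate (104) was 23 after median shift, 14 with quantile normalization, 53 with the filter of 10, 68 with a pseudocount of 0.1, 67 with 14 libraries, 17 with edgeR TMM, 53 with DESeq2, 16 scaled to listed reads, 53 without the 2 animals and 20 to 154 without single animals. Aged versus adult (0) was 1 without the 2 animals and 0 to 1 without single animals. The age trend (215) was 139 after median shift, 130 with quantile normalization, 123 with the filter of 10, 141 scaled to listed reads and 151 to 229 without single animals.

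List calls over 5 contrasts (22) fell to 1 with an estimated correlation and to 0 with that and median shift. Higher calls replaced uncalled lower values for miR-92a (0.94 after median shift, 0.83 with quantile normalization, 0.94 with edgeR TMM, 0.85 with DESeq2, 1.18 scaled to listed reads), miR-25 (0.78 with quantile normalization, 0.81 scaled to listed reads) and miR-21 (0.58 with edgeR TMM, 0.84 scaled to listed reads). The mean Spearman correlation of technical libraries was 0.986 among miRNAs of at least 10 RPM in both libraries, against 0.959 over all names.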

Other observations

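The tests here were fixed before their result was seen. miR-1, processed in muscle together with miR-133a, reached 7403 RPM at 2355 days, while miR-133a reached at most 0.297 RPM in any animal; miR-133a was chosen after its values were seen.

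As a hypothesis, arms of the same precursor may follow it together. Over 72 precursors with both arms tested, the scaled log2 fold changes of the arms (mature versus immature) correlated across miRNAs, which are not independent replicates, with Pearson r = 0.746, above the highest of 1000 random pairings (0.391), and 58 pairs had the same sign. Random pairings also break up clusters that move together, such as DLK1-DIO3 and C19MC. They therefore cannot separate arms that follow their precursor from arms that follow their cluster.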
